A study of Mus musculus with 5 samples.

How the data were processed

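Droplet-based single-cell RNA sequencing was done on whole testes of synchronized mice at 0, 144, 350.4, 556.8 and 763.2 h, 1 library per time. Per the labels' protocols, testes were digested with collagenase and DNase, the tubules were left to settle and the supernatant was taken off several times, trypsin and DNase then freed the cells, and the suspension was strained. The deposited files hold raw UMI counts per gene and barcode for 27998 features, written by Cell Ranger 3.0.2 per the file headers. The build mm10 and Seurat 4.3.0.1 are named in the submitters' processing notes, without their role. Settings of alignment and cell calling are not given in the sources used here. The lowest barcode totals were 909, 500, 692, 2443 and 1821 UMIs in time order, so the lower bound of the deposited barcodes differed between libraries. Each library was 1 group, taken from the sample titles.

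Cells were kept with at least 1000 UMIs, at least 500 genes and under 20% mitochondrial UMIs, limits set before the data were examined, as were the markers, gene lists, rule for named genes and most of the other settings tried. These removed 235, 2254, 1677, 0 and 0 barcodes for low content and 38, 607, 916, 562 and 512 for mitochondrial share in time order. Doublets were scored with Scrublet in scanpy 1.11.5 (expected rate 0.08). Its automatic thresholds called 0, 659, 5, 3 and 0 barcodes, so next to none outside the 144 h library. A score of 0.25 was used in every library instead, chosen after seeing this. It removed 197, 334, 229, 325 and 422 of the barcodes that passed the other limits. This left 7689, 6368, 4619, 8414 and 11053 cells. Counts were scaled to 10000 per cell and log-transformed. Cells of all libraries were clustered together on 3000 variable genes chosen within libraries and combined, without mitochondrial genes and without list genes other than markers. A graph of shared neighbours (40 principal components, 15 neighbours) was partitioned with the Leiden method of python-igraph 0.11.9 at resolution 2, which gave 89 clusters.

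A cluster took the name of the class with the highest mean marker score (log2 of its CPM plus 20 over the mean of all clusters) where that was at least 0.75, led the next class by at least 0.25, rested on at least 3 markers of at least 20 CPM, and no other class had more markers among the 10 leading genes. A cluster over 3 times shallower than its libraries with none of its own markers among those 10 was not named. Clusters that failed this were kept as germ cells without a stage where their best 2 classes were both germ cells, the score was at least 0.2, at least 3 markers were seen and no somatic marker was among the 10. These scoring thresholds were set after the data were seen, and unnamed clusters held 10.8%, 1.19%, 4.42%, 0.131% and 6.73% of kept cells. Markers covered 15 classes: Sertoli, 6 germ cell stages, Leydig, peritubular myoid, stromal, endothelial, macrophage, lymphocyte, vessel mural and red blood cells.

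Cells are not replicates, so UMIs were summed over the cells of a class in each library and given as CPM of the summed counts. A ratio of CPM has an exact 95% interval from the conditional binomial distribution, a share an exact binomial (Clopper-Pearson) interval. A share of 0 is given with the limit that 3 counts allow. In list medians and step sizes 3 counts stand in place of 0, and named genes with 0 counts are given by their interval bound. A library with under 20 cells of a class gave no value for it. No test was made. Sertoli-like sums held 33709938 UMIs at 0 h, 29457763 at 144 h, 3059348 at 350.4 h and 1155852 at 556.8 h. Since 14 Sertoli-like cells remained at 763.2 h, its comparisons used cells of under 50% mitochondrial UMIs clustered anew, with 35018346, 2386475 and 1543024 UMIs at 0, 556.8 and 763.2 h.

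The named genes were the 8 highest and 8 lowest for each pair of neighbouring times and the 12 highest and 12 lowest for 763.2 against 0 h, ranked by the interval bound nearest 1. They needed at least 50 UMIs and 50 CPM in the higher library, at least 2 times the CPM of all germ cells and no less than that of all cells of that library, and an interval wholly beyond 2-fold. In Leydig-like, peritubular-myoid-like, undifferentiated-spermatogonia-like and macrophage-like cells up to 5 each way were named against all cells outside the class, between the first and last library with at least 30 cells. Mitochondrial, ribosomal protein and haemoglobin genes and predicted gene models or clones were left out. Example members of lists, and Meig1, were picked after their values were seen.

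The 20 fixed lists were immature Sertoli, mature Sertoli, androgen responsive, FSH receptor and inhibin, retinoid, cell junction, germ cell niche factors, Notch, glucose and lactate, engulfment and lysosome, cholesterol synthesis, cell division, secreted proteins and inhibitors, basement membrane, dissociation response, spermatid RNA, adult Leydig, immature or fetal Leydig, spermatogonial response to retinoic acid and spermatogonial self renewal. The lists share some members. A list's value is the median log2 ratio of members with at least 10 UMIs over both libraries (at least 3 such members), with an interval from 1000 draws of members and UMIs and its percentile among 10000 random lists matched on mean CPM. Of the list symbols 2 were matched through their gene ID and 2 were not matched. The step size was computed after thinning each sum to the smallest total (1155852, or 1543024 for comparisons with 763.2 h). Coordinates come from GENCODE vM21 on GRCm38 by gene ID, where 446 of 446 IDs looked up were found.

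Results were recomputed, by plan, with a looser filter (500 UMIs, 250 genes), a limit of 10% mitochondrial UMIs, no doublet removal, Leiden resolutions 1 and 3, each library clustered alone, median-of-ratios size factors over genes of at least 50 CPM, subtraction of the library's own profile as free RNA (share set from germ cell markers of at least 50 CPM, a minimum set after the data were seen), the mean over cells, thinning of cells to 5000 UMIs (the number chosen after the data were seen), a minimum of 50 UMIs per list member, a pseudocount of 10 CPM and a minimum of 200 CPM for the step size. The share subtracted as free RNA was 10.7%, 2.92%, 18.9% and 18.4% at 0, 144, 350.4 and 556.8 h. Under 50% mitochondrial UMIs it was 14.3%, 16.5% and 14.8% at 0, 556.8 and 763.2 h. Added after the data were seen were under 50% mitochondrial UMIs and at least 5000 UMIs, alone or with the other settings for comparisons with 763.2 h. The counting interval was tested on simulated Poisson counts with 100 genes changed 2-fold and 100 changed 4-fold. The interval assumes such counts, so the test checks its computation and not variation between cells or libraries. For 144 against 0 h it held the true ratio for 95.7% of 15883 genes, for 350.4 against 144 h for 96.4% of 14707 and for 556.8 against 350.4 h for 96.3% of 11229. The direction of 4-fold changes was found for 100% of genes in each, and intervals lay wholly beyond 2-fold for 100%, 100% and 95% of them. For 2-fold changes, which lie on that bound, intervals were wholly beyond it for 2%, 4% and 0%. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.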

Results

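Single-cell RNA profiles were collected from whole testes of mice at 5 times, 0, 144, 350.4, 556.8 and 763.2 h, after synchronization of spermatogenesis. The series title names the maturation of Sertoli cells, the somatic cells that nurse germ cells inside the seminiferous tubule, while the cycle of the tubule epithelium is being set up. Its design text places the samples at successive returns of stages VIII to IX of that cycle. The 144 h sample lies 144 h after the 0 h sample, and each later sample lies 206.4 h after the one before. Each time had 1 library. No difference below therefore has a replicate check or a test, and intervals (95%) cover counting error only. The differences describe these libraries, not the conditions. The libraries at 0, 144, 350.4, 556.8 and 763.2 h held 8159, 9563, 7441, 9301 and 11987 barcodes. They summed to 75578147, 112142529, 96256872, 118147393 and 116745642 UMIs, with medians of 4028, 7551, 2864, 6099 and 3075 UMIs per barcode.

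The first question was which cells the testes held at each time. The libraries went from somatic cells and early spermatogonia at 0 h to mostly germ cells at 556.8 and 763.2 h, many of them meiotic or postmeiotic. Undifferentiated-spermatogonia-like cells, the class that holds the stem cells, made up 21.6% of kept cells at 0 h (1659 of 7689, 95% exact binomial interval 20.7 to 22.5), 4.54% at 144 h and 1.73% at 350.4 h. None were named at 556.8 or 763.2 h (limits from counting alone 0.0357% and 0.0271%), and the germ cells without a stage are not excluded from holding some. Early-meiotic-spermatocyte-like cells made up 3.80% at 144 h, 3.44% at 350.4 h, 12.8% at 556.8 h and 3.25% at 763.2 h. Pachytene-or-later-spermatocyte-like cells were named for 0.714% at 350.4 h (33 of 4619), 57.6% at 556.8 h (4843 of 8414, 56.5 to 58.6) and 40.2% at 763.2 h. Round-spermatid-like cells made up 3.40%, 2.72% and 22.5% (2486 of 11053, 21.7 to 23.3) at the last 3 times, and elongating-spermatid-like cells 0.152%, 9.96% and 9.88%. Germ cells whose clusters could not be given a stage made up 36.2% at 144 h, 71.3% at 350.4 h, 15.4% at 556.8 h and 16.5% at 763.2 h. Among them were cluster 14 (690 cells, 99.4% from 350.4 h) and cluster 34 (364 cells, 97.8% from 350.4 h). Both scored highest for early meiotic spermatocytes. Their leading genes include Psma8, Gml and Stambp, as do those of cluster 26 (named pachytene or later, mostly 763.2 h). The pachytene-or-later share at 350.4 h therefore depends on that naming. No cluster was named differentiating spermatogonia, but 5 clusters of germ cells without a stage had it as their best class. The nearest were cluster 18 (mostly 763.2 h, 0.733) and clusters 46 and 15 (mostly 144 h, 0.716 and 0.703), against a minimum score of 0.75 that was set after the data were seen. Other settings did name the class, with 917 cells at 144 h and 348 at 763.2 h at resolution 1. Shares of germ cell stages moved with the settings: at 350.4 h the early meiotic share ran from 2.06% to 28.8%, the pachytene-or-later share from 0.606% to 2.14%, the round spermatid share from 0.937% to 6.38% and the undifferentiated share from 0.863% to 2.89%. The early meiotic share at 144 h ran from 0.356% to 5.43%, the undifferentiated share there was 1.79% with a looser cell filter, and the round spermatid share at 556.8 h was 4.54% with each library clustered alone. Among cells of at least 5000 UMIs the early meiotic share was 20.5% at 556.8 h, and at 763.2 h the early meiotic, pachytene-or-later and elongating spermatid shares were 10.6%, 15.2% and 17.2%.

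Among somatic cells, Sertoli-like cells made up 37.2% of kept cells at 0 h (2862 cells, 36.1 to 38.3), 36.9% at 144 h (2351, 35.7 to 38.1), 11.6% at 350.4 h (535, 10.7 to 12.5), 0.547% at 556.8 h (46, 0.401 to 0.729) and 0.127% at 763.2 h (14, 0.0693 to 0.212). Leydig-like cells, the makers of androgen, went from 4.96% to 2.70%, 0.173%, none (up to 0.0357% from counting alone) and 0.0724%. Stromal-like cells went from 10.5% to 6.53%, 0.195%, 0.0475% and 0.109%. Macrophage-like cells went from 3.11% to 0.503%, 0.563%, 0.261% and 0.163%, and peritubular-myoid-like cells, the contractile cells around the tubule, from 5.50% to 6.31%, 2.14%, 0.606% and 0.452%. The dissociation let the tubules settle repeatedly and discarded the supernatant, which takes away cells between tubules, so the shares describe the suspensions. Among cells of at least 5000 UMIs macrophage-like cells made up 0.421%, 0.650%, 0.896%, 0.361% and 0.0605%, and 93.7% of those at 0 h lay below that depth, and peritubular-myoid-like cells 1.12% at 763.2 h. Leydig-like cells made up 0.244% and 0.242% at 350.4 and 763.2 h in that setting, and 0.411% and 0.208% with each library clustered alone. Under 10% mitochondrial UMIs the Leydig-like and stromal-like shares were higher at 144 h (3.47% and 9.20%) than at 0 h (3.08% and 8.21%), and at resolution 1 the peritubular-myoid-like share was lower at 144 h (6.34%) than at 0 h (6.78%). The Sertoli-like share at 144 h ran from 15.3% to 36.9% over the settings tried, and 1088 of its 2351 cells belong to cluster 8, of median 1654 UMIs, against a median of 12603 UMIs over the kept cells of that library. At 763.2 h the 744 unnamed cells (6.73%) all lay in cluster 12, whose leading genes include the Sertoli genes Ptgds, Tsx, Cst9 and Rhox5 but whose marker score was highest for round spermatids (0.956) and next for elongating spermatids (0.908). They are not counted as Sertoli-like, so the share at 763.2 h depends on that naming. At 350.4 h it was 3.22% among cells of at least 5000 UMIs and 18.7% with a looser cell filter, and in the last 2 libraries it was 1.16% and 0.659% when cells of up to 50% mitochondrial UMIs were kept.

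**Figure D1:**
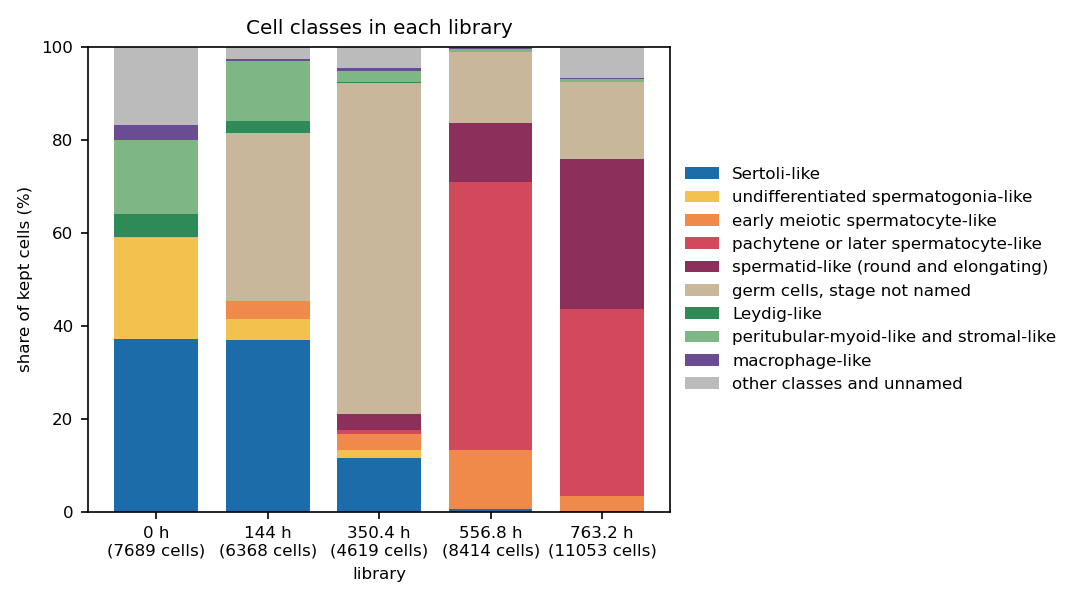
Share of kept cells (%) in each class, stacked from 0 to 100, for the 5 libraries, with the number of kept cells under each bar. Cells named Sertoli-like go from 37.2% at 0 h to 0.127% at 763.2 h, where cluster 12 (6.73%, led by Sertoli genes) is left unnamed, and pachytene-or-later-spermatocyte-like cells reach 57.6% at 556.8 h.

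The comparison of 144 with 0 h asked how Sertoli-like cells differed at the first return of the stage. Most genes of dividing cells and 5 of 10 genes of the immature state were at least 2-fold lower, and 7 of 9 androgen responsive genes were at least 2-fold higher. Amh, which encodes the hormone of immature Sertoli cells that makes the Müllerian duct regress, went from 417 to 50.3 CPM, 0.121 times its 0 h level (0.114 to 0.128). Hsd17b1, a steroid-converting enzyme, stood at 0.0574 times (0.0514 to 0.0639). Mki67, a marker of cycling cells, went from 94.7 to 2.38 CPM, 0.0251 times (0.0195 to 0.0318). Rhox5, an X-linked homeobox gene that androgen switches on in Sertoli cells, was 6.11 times higher (5.67 to 6.58), and Espn, an actin-bundling protein of the Sertoli cell's junctions with germ cells, was 5.60 times higher (5.38 to 5.83).

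By list, 13 of the 15 measured cell division genes were at least 2-fold lower at 144 h and 2 lay between, Cdk1 at 0.600 and Mcm3 at 0.584 times, and the median log2 ratio was −2.81. Of the 10 immature Sertoli genes, 5 were at least 2-fold lower and 5 lay between (median −2.02), with Thra, a thyroid hormone receptor, at 0.581 times. Of the 9 androgen responsive genes, 7 were at least 2-fold higher, among them Eppin (3.29 times), B4galnt1 (8.66 times) and Corin (33.6 times), while Tubb2b, a tubulin, was lower and Pcsk4 lay between (median 1.72). Of the 13 mature Sertoli genes, 7 were higher, 1 lower and 5 between (median 1.07). The medians of these 4 lists lay at percentiles 0, 0.02, 100 and 100 of random lists of like size and expression. Of the 12 germ cell niche factors 7 were at least 2-fold lower, 2 higher and 3 between (median −1.42), with Gdnf, which maintains spermatogonial stem cells, at 0.401 times, Wnt6 at 0.351 times and Kitl, the ligand of the Kit receptor, at 0.547 times. Of the 14 retinoid genes 6 were higher, 3 lower and 5 between (median 0.80), including the retinol dehydrogenase gene Rdh10 (9.84 times). Cyp26a1, which degrades retinoic acid, was 204 times higher (interval from 56.1 upward, 2 counts at 0 h). Of the 15 glucose and lactate genes 3 were higher, 2 lower and 10 between (median 0.70), with the lactate carrier Slc16a1 at 6.71 times and the lactate dehydrogenase gene Ldha at 0.386 times. Of the 15 junction genes 4 were higher, 1 lower and 10 between (median 0.69), with Cldn3, a tight junction protein, at 6.51 times (3.80 to 11.9). Of 10 Notch genes 4 were higher and 3 lower (median −0.17), with the Notch target Hey1 at 15.4 times.

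Genes named by the size rule at 144 h were Tpbgl (2429 times higher, interval from 436 upward, 1 count at 0 h), Sncb, which encodes beta-synuclein (668 times, 260.4 to 2453), Esyt3 (155 times), Lpar3, a lysophosphatidic acid receptor (145 times), Tmem255a (68.7 times), Tsx, a testis-specific X-linked gene (51.7 times, 43.6 to 61.7), Bik (38.3 times) and Hopx (24.5 times). Lower by the rule were 4 histone genes, Hist1h3c (0.0129 times), Hist1h2ae (0.0196 times), Hist2h2ac (0.0359 times) and Hist1h1b (0.0371 times), together with Serpinf1 (0.0241 times), Hsd17b1, Lbh (0.0612 times) and Lpl, which encodes lipoprotein lipase (0.0633 times). Sertoli-like cells came mostly from clusters 3, 13 and 19 at 0 h and from clusters 8, 10 and 20 at 144 h. Of these 16 genes 10 moved by over 1.5 times in at least 1 alternative and none turned, while 10 of 20 list medians moved as far and 4 changed sign, among them Notch, and the immature Sertoli median ran from −3.64 to −0.48.

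Between 350.4 and 144 h, the second return against the first, 5 of 8 androgen responsive genes were at least 2-fold higher, while 7 of 14 retinoid genes were at least 2-fold lower, or 5 of 14 with cells of up to 50% mitochondrial UMIs. Rhox5 went from 149 to 613 CPM, 4.11 times (3.90 to 4.34), and Cldn3 from 3.09 to 57.5 CPM, 18.6 times (14.4 to 24.3). Aqp8, a water channel, was 44.0 times higher (37.0 to 52.6). Rdh10 and Stra6, the retinol uptake receptor, stood at 0.0664 and 0.206 times. Amh changed little, at 0.819 times (0.677 to 0.983).

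Of the 8 measured androgen responsive genes 5 were at least 2-fold higher, none lower and 3 between (median log2 ratio 1.54, percentile 100), with Eppin at 2.12 times, Corin at 3.96 times and Tubb3 at 0.591 times. Of the 14 retinoid genes 7 were at least 2-fold lower, 1 higher and 6 between (median −0.66, percentile 0.06), but with cells of up to 50% mitochondrial UMIs 5 were lower, none higher and the median was −0.20, inside the random range (percentile 9.17). Of the 14 junction genes 3 were lower, Ocln (0.324 times), Jam3 (0.379 times) and Pvrl2 (0.436 times), Cldn3 was higher and 10 lay between (median −0.55, percentile 0). The basement membrane list had 4 of 12 lower and none higher (median −0.74), with the laminin gene Lamc1 at 0.401 times. The medians of the mature Sertoli list (−0.11) and the immature list (−0.29) lay within the range of random lists, at percentiles 23.4 and 11.7. Of the 15 cell division genes 8 were at least 2-fold higher and 7 between (median 1.37), with Mki67 at 8.25 times and 19.6 CPM. With the library's own profile subtracted as free RNA that median was −0.04, but most members then stood at the floor of 3 counts at 350.4 h. The spermatid list was higher beside the cell division list, with all 10 members up (median 8.49).

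Among the genes higher by the size rule were Aqp8, U90926 (22.4 times), Cldn3, Fyb (15.7 times), Svs5 (14.9 times), Ptgds, a prostaglandin synthase (14.4 times), and AY036118 (12.8 times). Among those lower were Shisa8 (0.0360 times), Sncb (0.0413 times, 0.0198 to 0.0760), Cxxc5 (0.0886 times), H2-Q10 (0.114 times), Fstl3 (0.123 times), Cidea, a lipid droplet protein gene (0.151 times), and Lgals1, which encodes a galectin (0.168 times, 0.149 to 0.188). At 350.4 h, 465 of the 535 Sertoli-like cells came from cluster 21, of median 1357 UMIs, and 64 deep cells from cluster 70. These 64 had a median of 31520 UMIs and so weigh far more in the sum than their number. Of the 16 genes the rule picked, 11 moved by over 1.5 times in at least 1 alternative and none turned, while 10 of 20 list medians moved as far and 9 changed sign, among them mature Sertoli and cell division, and Cldn3 came to a log2 ratio of 2.09 from 4.22 under a 10% mitochondrial limit.

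Between 556.8 and 350.4 h, Amh was lower again, at 14.7 against 41.2 CPM, 0.357 times (0.202 to 0.595). The androgen responsive genes Rhox5 and Eppin were lower, with Rhox5 at 0.454 times (0.402 to 0.512) and Eppin at 0.479 times (0.420 to 0.545), while Cldn3 stood at 1.02 times (0.761 to 1.36), or 1.45 times (1.22 to 1.71) with cells of up to 50% mitochondrial UMIs. Some genes of sugar use were higher, with Ldha at 3.44 times (2.94 to 4.01), the glucose carrier gene Slc2a3 at 3.37 times (2.72 to 4.18) and Pfkp, a phosphofructokinase, at 13.0 times (6.72 to 27.6). Lgals1 came back from 95.5 to 765 CPM, 8.01 times (7.01 to 9.18).

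Of the 6 measured immature Sertoli genes 3 were at least 2-fold lower and 3 between (median −1.20, percentile 0). Of the 13 mature Sertoli genes 3 were lower, among them Rhox5 and Eppin, and 10 between (median −0.41). Of the 8 androgen responsive genes 2 were lower and 6 between (median 0.04). Of the 15 glucose and lactate genes 6 were at least 2-fold higher, 1 lower and 8 between, the lower one being the lactate carrier gene Slc16a3 (0.132 times). Their median was 0.35 (percentile 98.4), ran from −0.26 to 0.69 over settings and lay inside the random range with cells of up to 50% mitochondrial UMIs (percentile 97.04). The Notch list had 2 of 5 lower (median −0.79), Notch1 at 0.265 times and Notch2 at 0.414 times. The cholesterol synthesis list had 3 of 14 lower and 1 higher (median −0.67), and the cell division list 5 of 15 lower and 2 higher (median −0.72). The dissociation response list, genes that enzyme treatment of tissue switches on, had 5 of 13 lower and 1 higher (median −0.66), with Fos at 0.440 times. That median was 0.43 when every cell weighed the same. The cell division median was 0.71 with free RNA subtracted, which leaves most of that list at the floor of 3 counts at 350.4 h.

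Besides Lgals1, the size rule named as higher Gatsl3 (7.84 times), Sowahd (7.25 times), Tmem255a (6.41 times), Nacc2 (5.82 times), Esyt3 (5.59 times), Cidea (5.48 times, 4.58 to 6.58) and Uchl1, a ubiquitin hydrolase (5.18 times). Lower were U90926 (0.0754 times), Slc16a3, Atf3, a stress-induced transcription factor (0.187 times), Mt3 (0.193 times), Mgp (0.204 times), Id3 (0.220 times), AY036118 (0.240 times) and Gsta2, a glutathione transferase (0.256 times). All 46 cells at 556.8 h lay in cluster 70, which held 64 of the 535 cells at 350.4 h, so the cells compared differ in depth. The values rest on summed UMIs, and those 64 cells had a median of 31520 UMIs against 1357 in the 465 cells of cluster 21. They therefore weigh far more in the 350.4 h sum than their number. Of the 16 genes 14 moved by over 1.5 times in at least 1 alternative and none turned, while 14 of 19 list medians moved as far and 15 changed sign, all but immature Sertoli, mature Sertoli, cholesterol synthesis and niche factors. Among the genes that moved were Id3, with a log2 ratio of −0.10 against −2.19 when cells were thinned to 5000 UMIs, and Lgals1, at 15.1 times with cells of up to 50% mitochondrial UMIs.

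At 763.2 h only 14 Sertoli-like cells passed the 20% mitochondrial limit, too few for a value, so both comparisons of that time used cells of up to 50%, a limit chosen after the data were seen, with 76 cells at 763.2 h, 103 at 556.8 h and 3049 at 0 h, and without the unnamed cells led by Sertoli genes. Against 556.8 h, the prostaglandin synthase gene Ptgds was 12.2 times higher (10.5 to 14.3), Aqp8 6.03 times higher (4.97 to 7.37) and Rhox5 1.77 times (1.59 to 1.98). Inha, the alpha subunit of inhibin, went from 1501 to 798 CPM, 0.532 times (0.498 to 0.568). Hsd17b1 was 9.54 times higher (3.99 to 27.6), at 24.0 CPM, while Amh stood at 1.43 times (0.785 to 2.59). The immediate early gene Fos was lower, at 0.273 times (0.213 to 0.346).

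Of the 12 measured dissociation response genes 5 were at least 2-fold lower and 7 between (median log2 ratio −0.77, percentile 0), with Egr1 at 0.441 times and Jun at 0.488 times. All 14 junction genes lay between 2-fold lower and 2-fold higher (median −0.04). Of the 13 mature Sertoli genes 1 was higher and 12 between (median 0.41), of the 8 androgen responsive genes Corin was higher (2.36 times) and 7 lay between (median 0.05), and of the 5 immature Sertoli genes Hsd17b1 alone was higher (median 0.46). Of 4 niche factors Wnt6 was higher (3.29 times, median 0.53), and of 6 FSH receptor and inhibin genes 1 was higher and 2 lower (median −0.48). Of 10 spermatid genes 5 were at least 2-fold higher and 5 between (median 0.84).

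Among the genes the size rule named as higher were S100a1 (121 times, 33.1 to 1011, from 2 counts at 556.8 h), Igfbp7 (66.5 times), Serpina3a (21.7 times), Ptgds, Tenm3 (6.61 times), Aqp8 (6.03 times) and the prion protein gene Prnp. Lower were the chemokine gene Cxcl1 (0.132 times), Fos, Gadd45b (0.289 times), Ptms (0.292 times), Tesc (0.299 times), Ier3 (0.309 times), Col18a1 (0.315 times) and Timp3, a metalloproteinase inhibitor (0.350 times). Cluster 68 of that clustering held 102 of the 103 cells at 556.8 h and 75 of the 76 at 763.2 h. Of the 16 genes the rule picked, 12 moved by over 1.5 times in at least 1 alternative and none turned, while 7 of 18 list medians moved as far and 9 changed sign, junction among them, and Fos came to a log2 ratio of −0.49 from −1.87 among cells of at least 5000 UMIs under the 20% limit.

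From 0 to 763.2 h, the whole span, 6 of 10 immature and 10 of 15 cell division genes were at least 2-fold lower in Sertoli-like cells, and 7 of 9 androgen responsive genes at least 2-fold higher. Amh went from 409 to 15.6 CPM, 0.0381 times (0.0244 to 0.0566), and Hsd17b1 stood at 0.118 times (0.0833 to 0.163). Rhox5 went from 23.7 to 453 CPM, 19.1 times (17.3 to 21.2), Cldn3 from 0.743 to 97.9 CPM, 132 times (86.5 to 208), and Espn from 84.0 to 1059 CPM, 12.6 times (11.9 to 13.4). Mki67 stood at 0.113 times (0.0642 to 0.183). On GRCm38 with GENCODE vM21 annotation, Amh (ENSMUSG00000035262) lies on chromosome 10 from 80805243 to 80807648, Rhox5 (ENSMUSG00000095180) on chromosome X from 37804842 to 37808876, Cldn3 (ENSMUSG00000070473) on chromosome 5 from 134986214 to 134987472 and Tsx (ENSMUSG00000031329) on chromosome X from 103414467 to 103424580.

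Of the 10 immature Sertoli genes 6 were at least 2-fold lower and 4 between (median log2 ratio −1.82, percentile 0.02). Of the 9 androgen responsive genes 7 were higher, 1 lower and 1 between (median 2.33, percentile 99.96), and of the 12 mature Sertoli genes 5 were higher, 2 lower and 5 between (median 0.67). Of the 15 cell division genes 10 were lower and 5 between (median −2.14, percentile 0), with Ccnb1 at 1.01 times. Of the 11 niche factors 6 were lower, 1 higher and 4 between (median −1.46), with Kitl at 0.364 times, Gdnf at 0.315 times and Wnt6 at 0.181 times, while Wt1, a transcription factor of Sertoli cells, stood at 1.93 times. Of the 14 cholesterol synthesis genes 7 were lower, 1 higher and 6 between (median −1.04, percentile 0.14), with Fdps at 0.166 times and Insig1 at 0.220 times. Of the 15 glucose and lactate genes 5 were higher, 2 lower and 8 between (median 0.28), with Slc16a1 at 5.76 times, Slc2a3 at 8.83 times and Pfkp at 15.3 times. Of the 15 engulfment and lysosome genes 3 were higher, 2 lower and 10 between (median 0.55), with the engulfment receptor gene Mertk at 4.07 times and Elmo1 at 6.55 times. The retinoid (0.26) and junction (0.09) medians lay within the range of random lists, at percentiles 66.7 and 60.8. Of the 13 dissociation response genes 7 were lower and 6 between (median −1.57), with Fos and Egr1 both at 0.138 times.

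The size rule named as higher Aqp8 (log2 ratio 13.49, from 1 count at 0 h), Trpc5os (interval from 524 times upward, 0 counts at 0 h), Tpbgl (2633 times, from 1 count), Gp1bb (743 times), Corin (378 times), Gpr55 (282 times), Tsx (212 times, 178 to 254), Ano1, a chloride channel (187 times), Itpr2 (150.4 times), Cldn3, Tmem255a (124 times) and Lpar3 (119 times). Lower were Shisa8 (0.00211 times), Akr1cl (0.00337 times), Mt3 (0.00378 times), Pdlim4 (0.00526 times), Serpine2 (0.00538 times), Cyr61 (0.00549 times), Cnn3 (0.00594 times), Sh3bgr (0.00614 times) and Socs2 (0.0126 times). Also lower were Lpl, Gpx8 and Sel1l3, which had 0 counts at 763.2 h and intervals up to 0.0183, 0.0231 and 0.0269 times. Shisa8 and Cyr61 rest on 1 count and Akr1cl, Mt3, Serpine2, Cnn3 and Sh3bgr on 2 counts at 763.2 h, and different clusters hold the class, 3, 13, 25 and 65 at 0 h and 68 at 763.2 h. Of the 24 genes 22 moved by over 1.5 times in at least 1 alternative and none turned, while 13 of 20 list medians moved as far and 9 changed sign, retinoid and junction among them. The immature Sertoli median ran from −2.80 to −0.50, the niche median from −2.46 to −0.09 and the cell division median from −2.44 to −0.98.

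**Figure D2:**
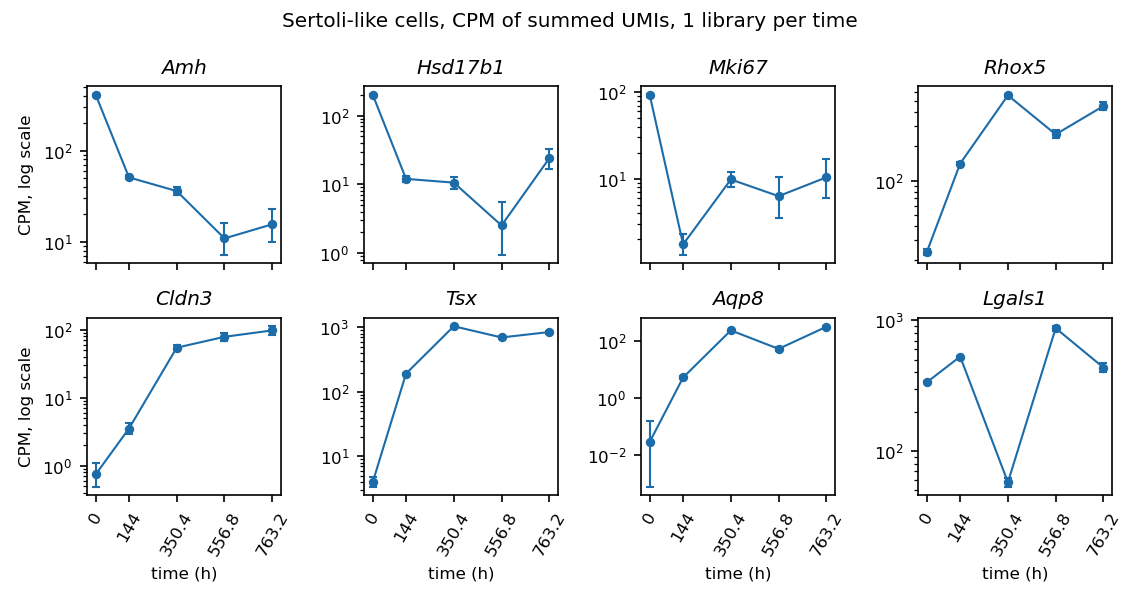
CPM (log scale) of 8 genes in Sertoli-like cells against time (h), from summed UMIs of cells of up to 50% mitochondrial UMIs, 1 library per time, with exact 95% Poisson intervals of the counts as bars. Amh falls from 409 to 15.6 CPM, Rhox5 reaches 563 CPM at 350.4 h, Cldn3 climbs to 97.9 CPM, and Lgals1 dips to 57.6 CPM at 350.4 h.

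**Figure D3:**
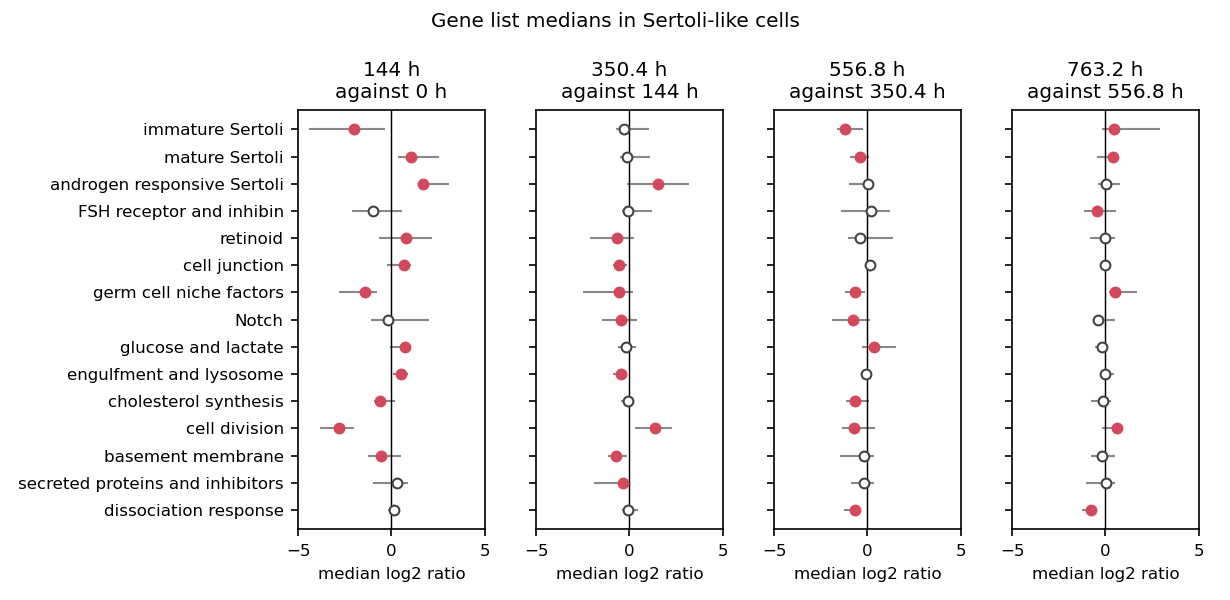
Median log2 ratio of 15 gene lists in Sertoli-like cells for the 4 pairs of neighbouring times, with 95% intervals from resampling members and UMIs as bars. Filled points lie outside the central 95% of 10000 random lists, open points inside. The first pair shows the immature Sertoli list at −2.02 and the androgen responsive list at 1.72.

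The size of each step was taken as the median absolute log2 ratio over genes of at least 50 CPM at equal totals of UMIs. It was 0.449 from 0 to 144 h (0.438 to 0.460, 3418 genes), 0.282 from 144 to 350.4 h (0.272 to 0.291), 0.327 from 350.4 to 556.8 h (0.318 to 0.336) and, with cells of up to 50% mitochondrial UMIs, 0.253 from 556.8 to 763.2 h (0.245 to 0.261). Over the whole span it was 0.653 (0.640 to 0.668). Counting noise alone gave 0.0976 to 0.114. Rank correlations of CPM across genes, which are not independent replicates, were 0.715, 0.819, 0.749 and 0.874 for the 4 steps and 0.482 for the whole span. Among cells of at least 5000 UMIs the step from 350.4 to 556.8 h was 0.660 and the last step 0.448 (the latter under the 20% limit), so the order of the steps was not settled. That setting was clustered and named anew, with 89 Sertoli-like cells at 556.8 h and 25 at 763.2 h. The main setting named 46 and 14, and none of the 46 had under 5000 UMIs. Membership of the class therefore changed as well as depth.

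Other classes were compared between the first and the last library that held at least 30 of their cells. In Leydig-like cells at 144 against 0 h, Hsd3b6, a steroid-making enzyme of adult Leydig cells, went from 4.58 to 699 CPM, 153 times (92.3 to 273), while the Leydig hormone gene Insl3 stood at 0.243 times (0.222 to 0.266). Of the 9 adult Leydig genes 3 were at least 2-fold higher and 2 lower (median 0.53), of the 8 immature or fetal Leydig genes none and 3 (median −0.05), and the cholesterol synthesis median was 0.48. Also named were Cxcl10 (132 times), Lmcd1 (11.1 times), Trf (9.73 times) and Cxcl1 (9.39 times) as higher, and Fabp4 (0.00564 times, from 2 counts at 144 h), Car3 (0.0383 times), Ly6d (0.132 times) and Cebpb (0.227 times) as lower, with a dissociation response median of 0.78. The class lay mostly in clusters 41 and 56 at 0 h and in cluster 41 at 144 h. In macrophage-like cells at 144 against 0 h, the chemokine genes Cxcl9, Ccl8 and Ccl5 were higher, each from 0 counts at 0 h. Their intervals ran from 129, 23.8 and 23.0 times upward. Cd209f was 77.0 times and the antigen-presenting H2-Aa 25.8 times higher, while Spp1 (0.152 times), Rpgrip1 (0.206 times), Hmox1 (0.223 times) and AY036118 (0.0146 times) were lower. Most of these cells came from cluster 52 at 0 h and from the deeper cluster 79 at 144 h, so different clusters and depths are compared. In these cells the engulfment median was 0.40 and the dissociation response median 1.38.

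In peritubular-myoid-like cells at 763.2 against 0 h, the genes named as lower were the imprinted H19 (0 counts, interval up to 0.0372 times) and Peg3 (0.0276 times, from 3 counts), together with Mgp (0.0740 times), Tcf21 (0.0768 times) and Stc1 (0 counts, interval up to 0.105 times). Tmem37 (124 times), Synm, an intermediate filament protein of muscle (20.4 times), Gadd45g (15.3 times), Anxa3 (8.94 times) and BC051019 (interval from 202 times upward, 0 counts at 0 h) were higher. The class lay mostly in cluster 28 at 0 h and in cluster 71 at 763.2 h, whose second score was for smooth muscle of vessels, so different clusters are compared. List medians there were −0.36 for basement membrane, 0.29 for retinoid, −1.03 for cell division, −1.43 for dissociation response and 10.78 for spermatid genes. In undifferentiated-spermatogonia-like cells at 350.4 against 0 h the rule named RP23-4H17.3 (3.44 times) and Tmem80 (0.284 times), most cells lying in cluster 4 at 0 h and in cluster 39 at 350.4 h. List medians there were 0.29 for self renewal, 0.17 for the response to retinoic acid, −0.02 for cell division and 0.43 for dissociation response, and all 9 measured spermatid genes were higher.

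Spermatid genes, such as the protamine gene Prm1, also gave UMIs in somatic classes. They made up 0.00731% of the UMIs of Sertoli-like cells at 0 h, 0.0139% at 144 h, 0.0944% at 350.4 h and 0.534% at 556.8 h (0.521 to 0.548), against 0.00447%, 0.00939%, 0.312% and 3.95% of all UMIs of those libraries. Peritubular-myoid-like cells held 0.00130%, 0.000634%, 0.0339% and 0.972%, and macrophage-like cells 1.53% at 556.8 h. Meig1, a list member that Sertoli-like cells held before spermatids were named, stood at 71.1 and 138 CPM there at 0 and 144 h. It made up nearly all of the list's UMIs in Sertoli-like cells at those times, and most of them at 350.4 h (601 CPM). At 350.4 h Meig1 was higher in pachytene-or-later-spermatocyte-like cells (7453 CPM) than in round-spermatid-like cells (5354 CPM). The list's shares up to 350.4 h therefore rest mostly on a gene that is not particular to spermatids.

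Mitochondrial transcripts took a higher share of the UMIs of Sertoli-like cells at each later time than at 0 h. Among cells of at least 5000 UMIs and up to 50% mitochondrial UMIs, the median share was 7.12% at 0 h, 15.6% at 144 h, 22.4% at 350.4 h, 20.8% at 556.8 h and 24.7% at 763.2 h. In peritubular-myoid-like cells it was 4.00%, 4.71%, 6.42%, 5.69% and 6.18%. A limit of 20% therefore removes more Sertoli-like cells from the later libraries, and their shares above carry that limit. The medians also depend on depth, as the minimum of 5000 UMIs kept 320 of 832 Sertoli-like cells at 350.4 h. Under the 20% limit and without that minimum, they were 5.04%, 11.6%, 9.73% and 17.0% at 0, 144, 350.4 and 556.8 h. There 350.4 h lay below 144 h.

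**Figure D4:**
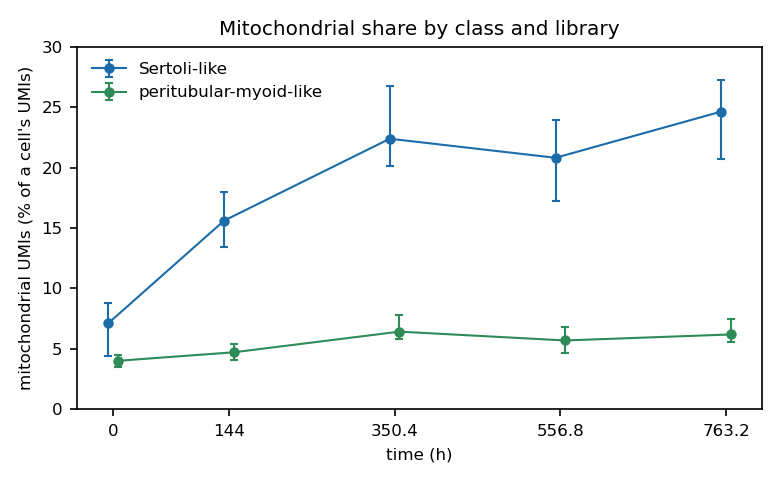
Median mitochondrial share of a cell's UMIs (%) against time (h) in Sertoli-like and peritubular-myoid-like cells of at least 5000 UMIs and up to 50% mitochondrial UMIs, with quartiles as bars. The Sertoli-like median goes from 7.12% at 0 h to 24.7% at 763.2 h, and the peritubular-myoid-like one from 4.00% to 6.18%.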

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

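The tests on peritubular-myoid-like cells and on the number of mitochondrial UMIs per cell were chosen after the result was seen, and the rank correlation was fixed before it. Cells of 20% to 50% mitochondrial UMIs lay outside the main measurement, and they held many Sertoli-like barcodes in the later libraries. They made up 15.01% of Sertoli-like barcodes under 50% at 144 h (13.2 to 16.9), 34.7% at 350.4 h (31.5 to 38.1), 54.4% at 556.8 h (44.3 to 64.2) and 81.6% at 763.2 h (71.0 to 89.6), against 0.328% at 0 h, which was above the level of the 0 h sample each time. These percentages leave out 2 unnamed clusters of that clustering. Cluster 5 (1102 barcodes, 99.8% from 144 h) scored highest for Sertoli, and cluster 8 (843 barcodes, 95.6% from 763.2 h) was led by Ptgds, with Tsx and Rhox5 among its leading genes. The percentages at 144 and 763.2 h depend on that naming. In the main clustering the unnamed cells at 763.2 h had a median mitochondrial share of 4.88%.

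The pattern is the Sertoli-like mitochondrial share at 763.2 against 0 h, a fold of 3.46 in the median. Shares, correlations and Sertoli-like UMI numbers in this paragraph are of cells of at least 5000 UMIs. Damage of all cells alike is argued against by peritubular-myoid-like cells, whose median rose 1.545-fold, 0.446 of the Sertoli-like fold. Loss of cytoplasmic RNA from Sertoli-like cells was predicted to make the share fall as nuclear-gene UMIs rise. The rank correlation was −0.589 over 76 cells at 763.2 h, −0.425 at 556.8 h, −0.453 at 350.4 h, −0.177 at 144 h and 0.407 at 0 h. This met the prediction, but nuclear-gene UMIs enter the share's denominator, so a negative value is partly built in. The correlation therefore cannot decide whether such a loss contributes. Median nuclear-gene UMIs per Sertoli-like cell were no lower at 763.2 h (14700) than at 0 h (14180). Loss as the whole cause is argued against, for these cells only, by their median number of mitochondrial UMIs, 4.311 times higher at 763.2 h. Peritubular-myoid-like cells, without that depth limit, were shallower at 763.2 h, at 0.510 times their 0 h depth. The limit kept 1546 of 3049 Sertoli-like cells at 0 h and all 76 at 763.2 h, where cluster 8 of that clustering (median 2147 UMIs) was unnamed. Cells that had lost RNA to below the limit could not enter, so loss in such cells was not tested. A higher mitochondrial RNA content of older Sertoli cells stays open and was not tested apart from time.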

How the results depend on the processing

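The settings under 50% mitochondrial UMIs and at least 5000 UMIs, and the depth of thinning, were chosen after the data were seen. No paired analysis was possible because each time had 1 library, and no test was made. Over settings, 4 of 20 list medians changed sign at least once at 144 against 0 h, 9 of 20 at 350.4 against 144 h, 15 of 19 at 556.8 against 350.4 h, 9 of 18 at 763.2 against 556.8 h and 9 of 20 at 763.2 against 0 h. Counted as turned were only 3 values, of medians whose interval excluded 0 and whose percentile lay outside the central 95%. Of the other values 1038 stayed within the median's interval and 58 did not, and both groups include sign changes of less certain medians. For 88 named gene ratios 636 stayed, 164 moved and 0 changed sign. All kept their direction beyond 2-fold except in 4 settings, which kept 87 of 88 when thinned, 47 of 48 at 5000 UMIs or more, 37 of 40 at 5000 UMIs or more under 20% and 39 of 40 with the looser filter under 20%. Under 10% mitochondrial UMIs no Sertoli-like cell was left at 556.8 or 763.2 h, and at least 5000 UMIs left 79 at 350.4 h, so these settings limit what can be said of the late libraries. Settings with another cell filter were clustered and named anew, so class membership changed with them. Under 50% mitochondrial UMIs Sertoli-like cells at 144 h numbered 1506 against 2351, though that limit is looser. There a cluster of 1102 barcodes, 99.8% of them from 144 h, scored highest for Sertoli (2.32) but stayed unnamed by the depth rule. Naming thus accounts for that drop, and the cause of the other values below was not tested.

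Sertoli-like shares (%) at 0, 144 and 350.4 h were 41.2, 15.3 and 18.7 with at least 500 UMIs and 250 genes, and 29.2, 23.4 and 7.88 under 10% mitochondrial UMIs (0 and 0 at 556.8 and 763.2 h). At all 5 times they were 39.5, 22.3, 16.3, 1.16 and 0.659 under 50%, and 45.6, 28.2, 3.22, 1.79 and 0.756 at 5000 UMIs or more. At 0 and 144 h they were 38.6 and 19.8 at resolution 1 and 33.9 and 29.7 with each library clustered alone. Resolution 3 gave 35.0 at 0 h, and no doublet removal 20.2 at 144 h and 12.6 at 350.4 h.

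The immature Sertoli median at 350.4 against 144 h was −0.95 under 10% mitochondrial UMIs and −0.81 as a mean over cells, and at 556.8 against 350.4 h −1.74 at 5000 UMIs or more. The 3 values that turned were the cell division median at 350.4 against 144 h (−0.041) and the spermatid median at 556.8 against 350.4 h (−3.29), both with free RNA subtracted, and the dissociation response median at 556.8 against 350.4 h (0.43 as a mean over cells).

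The step at 144 against 0 h was 0.503 with the looser filter, 0.461 under 10% mitochondrial UMIs, 0.434 without doublet removal, 0.548 thinned, 0.485 at 5000 UMIs or more and 0.553 for genes of 200 CPM. At 350.4 against 144 h it was 0.379 with the looser filter, 0.415 under 10%, 0.297 at resolution 1, 0.302 with free RNA subtracted, 0.412 as a mean over cells, 0.379 thinned, 0.266 under 50%, 0.322 at 5000 UMIs or more and 0.257 for genes of 200 CPM. At 556.8 against 350.4 h these were 0.359 with the looser filter, 0.312 without doublet removal, 0.313 with size factors, 0.304 with free RNA subtracted, 0.373 as a mean over cells, 0.436 thinned, 0.281 under 50%, 0.660 at 5000 UMIs or more and 0.312 for genes of 200 CPM. At 763.2 against 556.8 h the step was 0.300 with the looser filter under 20%, 0.244 with size factors, 0.322 thinned, 0.448 at 5000 UMIs or more under 20% and 0.241 for genes of 200 CPM. At 763.2 against 0 h it was 0.623 with the looser filter under 20%, 0.678 with free RNA subtracted, 0.707 as a mean over cells, 0.737 thinned, 0.619 at 5000 UMIs or more under 20% and 0.807 for genes of 200 CPM.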

Other observations

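The protamine ratio tests had their bounds set after the ratios were seen, and the doublet test had the words on a main source added after its value, while the test on cell division genes was fixed before its result. Further list medians in Sertoli-like cells had smaller or mixed changes. At 144 against 0 h the FSH receptor and inhibin list had 4 of 9 members at least 2-fold lower and 1 higher (median log2 ratio −0.97), with Inhba, which encodes the activin subunit beta A, at 0.121 times and the FSH receptor gene Fshr at 0.399 times. The cholesterol synthesis median was −0.60, with Idi1 at 0.452 times, and the engulfment and lysosome median 0.52, with the lipoprotein receptor gene Scarb1 at 4.15 times. The secreted protein list had 3 of 14 higher and 4 lower (median 0.28), with Timp2 at 7.93 times and Serpine2 at 0.0844 times, and the basement membrane list 2 of 12 higher and 3 lower (median −0.56), with Lamb2 at 4.74 times and Lamb1 at 0.0495 times.

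Some members of Leydig lists that Sertoli-like cells of the 0 h library held were lower later. Akr1cl went from 385 to 1.30 CPM between 0 and 763.2 h (2 counts), and Hsd17b3, a testosterone-making enzyme, from 113 CPM at 0 h to 17.1 CPM at 144 h. The adult Leydig median was −2.72 at 144 against 0 h and −1.11 at 763.2 against 0 h, and the immature or fetal Leydig median −2.25 and −0.35. Both kept their sign at 144 against 0 h in every setting, but at 763.2 against 0 h they ran from −1.41 to 1.17 and from −1.39 to 0.58. The self renewal median in Sertoli-like cells was −1.06 at 144 against 0 h (−1.89 to 0.73 over settings) and 1.75 (−0.00 to 3.78) at 763.2 against 0 h, where Etv5, a transcription factor that Sertoli cells also express, was 9.74 times higher (7.39 to 12.8). The list for the response to retinoic acid had medians of 0.51 (0.05 to 1.85 over settings) and 0.50 (as low as −0.33, with the sign changed in 1 setting) in the same comparisons. Lgals1, Cidea, Tmem255a and Esyt3 stood low at 350.4 h and high on either side in Sertoli-like cells, with Lgals1 at 570 CPM at 144 h, 95.5 CPM at 350.4 h and 765 CPM at 556.8 h.

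The next pattern is spermatid RNA in Sertoli-like cells. Doublets with a spermatid as the main source were tested by the cells holding at least 10 UMIs of the list. At 763.2 h 100% of the 76 cells did, but so did 100% of the 49 peritubular-myoid-like and 21 macrophage-like cells. RNA present in all classes passes that cut, so the test cannot tell how much doublets add. The list's UMIs were not confined to a few Sertoli-like cells (median 73.5, mean 94.1). The mean was 91.0 in peritubular-myoid-like and 69.2 in macrophage-like cells, at median depths of 6082 and 3717 UMIs against 19440. At 556.8 h the means were 115.6, 87.2 and 97.6 in Sertoli-like, peritubular-myoid-like and macrophage-like cells. The number per cell thus differed less between classes than depth did, and shares of UMIs differ partly through depth. At 556.8 h free RNA alone may account for the spermatid RNA, as the protamine to transition protein ratio was 1.062 times that of peritubular-myoid-like cells, within the bound of 1.2-fold. An earlier draft of the bound, an interval that holds 1, was replaced after the value was seen and would have argued against free RNA alone (1.006 to 1.122). At 763.2 h the sources cannot be told apart, since the ratio was 1.436 (1.359 to 1.517) over all cells but 1.157 (1.082 to 1.238) without the tenth of cells richest in spermatid UMIs, and uptake of spermatid remnants, which Sertoli cells are known for, was not tested. At 350.4 h, where no prediction was made, the ratio was 1.67 times that of peritubular-myoid-like cells (1.24 to 2.31) and 0.743 times that of macrophage-like cells (0.460 to 1.29), which leaves the source at that time open.

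The last pattern is the higher level of cell division genes in Sertoli-like cells at 350.4 h. Free RNA of dividing germ cells may account for it, since the list's median Sertoli-like CPM was 0.1656 of the library's CPM, below the 75th percentile (0.421) of the same ratio over 24 germ cell markers, whose median was 0.190. Subtracting the library's profile took the list's median log2 ratio from 1.37 to −0.04. The share subtracted, 18.9%, was set from the same 24 markers, so that value is not separate evidence. Most list members lay below that share and were set to the floor of counts at 350.4 h. The subtraction therefore cannot decide the source. Division of Sertoli cells at that time is not excluded by these values and was not tested.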
